A study of Mus musculus with 24 samples.

How the data were processed

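The data are 24 arrays of total RNA from single-cell suspensions of B16 tumours, 4 biological replicates in each of 6 groups: no treatment, Mock and IL-12TD, at day 3 and at day 7. Per the labels, the tumour cells were injected under the skin, and in the treated arms the mice were irradiated and received pmel-1 CD8+ T cells that were either not transduced (Mock) or transduced with IL-12 (IL-12TD). Groups were taken from the titles, source names and characteristics. The treatment text of the Mock day 7 samples names day 3, while every other field of these samples names day 7, and they were placed at day 7. The labels state no irradiation for untreated mice and no processing batch or scan date, so day and batch cannot be told apart.

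The deposited values are log2 intensities per probeset, made by RMA per the submitters' processing notes. The software and its version are not given, and whether all arrays were normalized together is not stated. The interquartile range of the log2 values, taken over the 19938 tested genes, averages from 2.22 to 2.76 between groups. This puts a joint quantile normalization of all arrays in doubt. It cannot decide the question, since the other probesets did not enter the range. The log2 unit was inferred from the deposited values, which run from 1.009 to 14.367, and from the usual output of RMA. The table holds 35556 probesets, of which 21789 list a single gene, 1621 list several genes and 12146 list no gene. Probesets with several genes or no gene were left out of the main tests of genes and lists. They entered only the setting with all probesets, counts of changed probesets, and values of shared globin and MHC class I heavy chain probesets. Symbols were matched to a reference list of mouse genes for 21698 probesets and kept from the platform table for 91. Where a gene had more than 1 probeset (999 genes) the probeset with the highest mean over all arrays was kept, which gave 19938 genes. The values of all pairs of arrays were compared, and 0 pairs were identical. The number of arrays per group limits the precision.

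Genes were tested with limma 3.58.1 in R 4.3.3 by a linear model with a mean for each of the 6 groups over all 24 arrays and moderated t statistics (lmFit and eBayes, default prior, two-sided), without an intensity filter. P-values were adjusted by Benjamini-Hochberg over all genes, and an adjusted p under 0.05 was called. Comparisons were IL-12TD with Mock, IL-12TD with no treatment and Mock with no treatment at each day, day 7 with day 3 in each arm, and the difference between the day 7 and day 3 effects of IL-12TD against Mock. A fold change is 2 to the power of the log2 difference.

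Before the data were examined, 30 gene lists were fixed from general knowledge: pathways and processes, and markers of cell types. Of these, 29 had at least 5 measured members and were tested in each comparison with camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. The same test with an estimated correlation and the fry test were run beside it. Counts of members that rose or fell are given over all genes and adjusted over the list alone; "by either count" means that the 2 counts were equal. Which genes are named was also fixed beforehand. For IL-12TD against Mock these were the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a change of at least 2-fold and no overlap between the 4 and 4 values, leaving out names that are only model or clone identifiers. To these were added up to 3 members of each list with the smallest adjusted p, and 14 measured genes named in every case, among them Ifng, Cd8a, Arg1 and Tyr. For the other comparisons the rule set the 5 largest changes each way and the same 14 genes. The text gives only part of the list members and, in those other comparisons, only part of the 14 genes.

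List scores relative to leukocytes are an array's mean log2 over a list minus its mean over the pan-leukocyte list, without shared members. They were compared by exact permutation tests over the 70 assignments of 4 against 4 arrays, for which the smallest p is 0.0286. The same exact test was used for the interquartile range. The overlap of calls between the days was set beside the number expected if the days were independent. Measures of single arrays were screened by Dixon's ratio within each group of 4 (threshold 0.829).

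Alternatives were a second quantile normalization over the tested genes, centring of each array on its median, removal of dim genes (above the 40th percentile of the array on at least 4 arrays, 13424 genes kept), a trended and robust variance prior, array weights, a fit on the compared groups only, replicate number as a block, the mean of a gene's probesets, all probesets of the table, and each array left out in turn. Leaving out 3 arrays that stand apart together was added after the results had been seen. The model was tested on simulated data, drawn around each gene's mean with its own residual spread and with changes added. At day 3 and day 7, 95.5% of changes of 1 log2 unit and 100% of 2 log2 units were recovered, and 26.9% and 43.3% of changes of 0.5, with 7 false calls among 170 and 10 among 182. The simulated genes were independent, the spread was the same on every array and few genes changed, so these rates may not hold for the real data. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.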

Results

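The series measured gene expression in mouse tumours grown from B16, a pigmented melanoma line, after transfer of T cells with or without interleukin 12 (IL-12). Per the labels, every mouse received 500000 B16 cells under the skin. In the treated arms the mice also received 5 Gy of total body irradiation and 100000 pmel-1 CD8+ T cells, which carry a receptor for the melanocyte protein encoded by Pmel. The transferred cells were either not transduced (Mock) or transduced to make IL-12 (IL-12TD). Tumours were taken at day 3 or day 7, dispersed to single cells, and their total RNA was put on Affymetrix whole-transcript arrays. There were 24 arrays in 6 groups of 4 replicates: no treatment, Mock and IL-12TD at each day. The number of arrays per group limits the precision, and 19938 genes were tested. Unless stated otherwise, changes are log2 differences ± SE of the limma model with n = 4 arrays per group, and group levels are means ± SD of log2 values.

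The arrays separated by day and by IL-12TD treatment. The first principal component held 35.5% of the variance and the second 27.2%. Replicates within a group correlated at r = 0.967 to 0.983 in IL-12TD day 3 and 0.983 to 0.992 in IL-12TD day 7. The lowest correlation within a group was 0.962, in no treatment day 7, where replicate 3 lay apart from the other replicates. The spread of values differed between groups: the interquartile range averaged 2.26 in IL-12TD day 3 against 2.76 in Mock day 3 and 2.76 in no treatment day 3 (exact permutation p = 0.0286 for both, two-sided). This is the smallest p that 4 against 4 arrays can give. At day 7 it averaged 2.45 in IL-12TD, 2.22 in Mock and 2.4 in no treatment. Arrays normalized together by quantiles usually differ less than this, but the range was taken over the tested genes only. A joint normalization of all arrays is therefore in doubt but not excluded, which limits comparisons of the range and of the days.

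**Figure D1:**
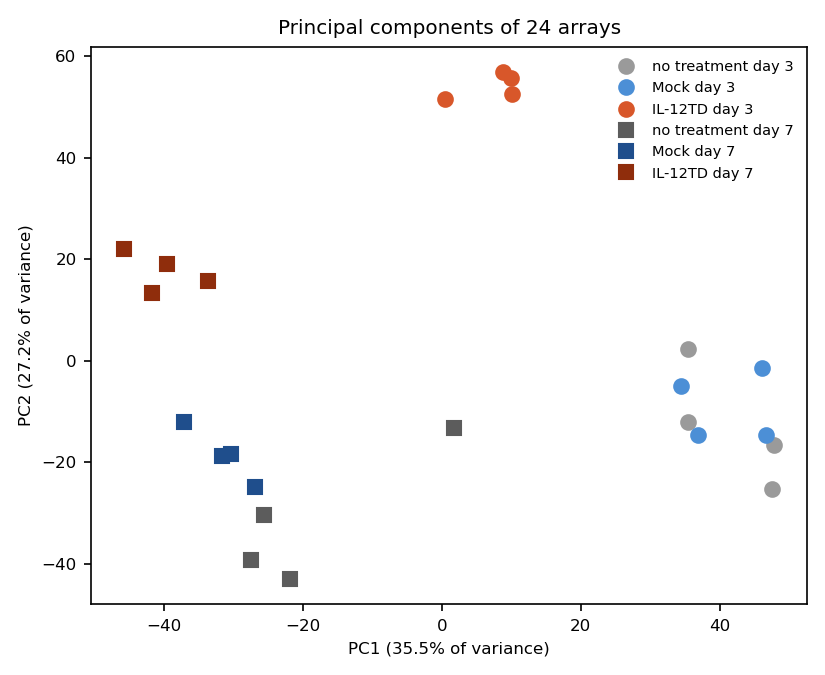
Principal components of the 24 arrays over the 19938 genes, with PC1 (35.5% of the variance) on the horizontal axis and PC2 (27.2%) on the vertical axis, and a point per array coloured by group. The IL-12TD arrays of each day lie apart from the other groups of that day, while the Mock and untreated arrays of day 3 lie among each other.

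The comparison of IL-12TD with Mock at day 3 asked what the IL-12 transduction added to irradiation and transferred T cells. Ifng and Gzmb rose most. Ifng, which encodes interferon gamma, was 52.8-fold higher (5.72 ± 0.28, adjusted p = 4.6e-14), at 11.74 ± 0.14 in IL-12TD and 6.02 ± 0.97 in Mock tumours. The granule proteases Gzmb and Gzma were 49.8-fold and 24.5-fold higher, and Nkg7, a cytotoxic granule membrane protein, was 16.2-fold higher. Cd3g, a chain of the T cell receptor complex, rose by 4.99 ± 0.36, and Il2ra, the alpha chain of the interleukin 2 receptor, by 4.87 ± 0.22. The remaining genes among the 8 largest rises were S100a8 (4.17 ± 0.25, adjusted p = 1.58e-12) and S100a9 (4.1 ± 0.26), calcium-binding proteins of neutrophils and monocytes.

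Every measured member of the T cell and NK effector list rose, 16 of 16, and 16 adjusted over the list alone, with a median of 2.82 (camera adjusted p = 7.92e-21). Of 12 IL-12 and STAT4 signalling genes, 10 rose over all genes and 10 adjusted over the list alone (median 1.97, camera adjusted p = 8.87e-12). Il12rb2, a chain of the IL-12 receptor, rose by 2.77 ± 0.18, and Tbx21, the transcription factor T-bet, by 2.35 ± 0.17. Of 16 T cell markers, 14 rose by either count, including Cd8a (8.02-fold, 3 ± 0.16, adjusted p = 2.49e-13), Cd3d (2.65 ± 0.16) and Lat (2.64 ± 0.15), with a median of 2.43 (camera adjusted p = 3.83e-19). Of 10 NK cell markers, 5 rose, among them Klrd1 (3.22 ± 0.21) and Il2rb (3.06 ± 0.32), and 8 rose adjusted over the list alone (camera adjusted p = 6.52e-05, adjusted p = 0.11 with an estimated correlation). Klrd1, Klrk1 and Eomes are also members of the T cell and NK effector list, so these lists overlap and do not separate NK cells from T cells. Of 12 immune checkpoint genes 11 rose by either count (median 1.6, camera adjusted p = 1.04e-10), with Cd274, the ligand PD-L1, 6.65-fold higher, and its receptor Pdcd1 (1.85 ± 0.15) and Havcr2 (2.33 ± 0.23) also higher. The probesets of the IL-12 subunit genes changed little: Il12a differed by 0.39 ± 0.13 (adjusted p = 0.0183) and Il12b by 0.31 ± 0.14 (adjusted p = 0.0792). Both were dim: Il12a lay at 4.93 ± 0.26 in IL-12TD and 4.54 ± 0.06 in Mock tumours, and Il12b at 4.57 ± 0.24 and 4.27 ± 0.27. The array medians averaged 5.42 and 5.44. Whether these probesets read the transduced IL-12 sequence is not stated, so they may not measure it at either day. The Il12a call was lost after a second quantile normalization (0.24, adjusted p = 0.179) and without IL-12TD day 3 replicate 3 (0.35) or replicate 4 (0.33). Il12b passed without Mock day 3 replicate 2 (0.39) or IL-12TD day 3 replicate 2 (0.4).

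Interferon-induced and antigen presentation genes rose together at day 3. All 20 measured members of the interferon gamma response list rose, and 20 adjusted over the list alone (median 2.09, camera adjusted p = 1.74e-17). The chemokine Cxcl9 was 7.64-fold higher (2.93 ± 0.5, adjusted p = 4.64e-05) and Nos2, the inducible nitric oxide synthase, 7.84-fold higher (2.97 ± 0.27). The guanylate-binding protein Gbp5 rose by 2.66 ± 0.24. All 21 type I interferon response genes rose by either count (median 1.47, camera adjusted p = 1.24e-15, adjusted p = 0.0545 with an estimated correlation). Oas3, an antiviral enzyme, rose by 2.83 ± 0.18 and the nucleic acid sensor Zbp1 by 2.84 ± 0.32. In the MHC class I presentation list 12 of 15 rose and 1 fell, adjusted over the list alone 12 and 1 (median 1.38, camera adjusted p = 1.45e-09, adjusted p = 0.0545 with an estimated correlation). They included the immunoproteasome subunit Psmb9 (2.45 ± 0.23) and the peptide transporter Tap1 (3.36-fold, 1.75 ± 0.26). In the MHC class II presentation list 6 of 9 rose, 6 adjusted over the list alone (median 1.61, camera adjusted p = 0.000648, adjusted p = 0.11 with an estimated correlation). The class II chain genes H2-Ab1 and H2-Aa rose by 2.43 ± 0.34 (5.39-fold) and 2.33 ± 0.32. The pan-leukocyte markers moved the same way: 14 of 14 rose, 14 adjusted over the list alone, with a median of 1.63 (camera adjusted p = 7.39e-11, adjusted p = 0.0587 with an estimated correlation). Ptprc, which encodes CD45, was 4.41-fold higher.

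Myeloid genes rose in part. Of 16 neutrophil and granulocyte markers 12 rose, 13 adjusted over the list alone (median 1.63, camera adjusted p = 1.23e-10), including Retnlg (2.28 ± 0.22). Of 18 macrophage and monocyte markers 7 rose, 7 adjusted over the list alone (median 0.56, camera adjusted p = 0.00166, adjusted p = 0.325 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 was 3.95-fold higher (1.98 ± 0.29) and Aif1 higher by 1.07 ± 0.21. In the costimulation and myeloid activation list 15 of 19 rose, 16 adjusted over the list alone (median 0.69, camera adjusted p = 3.89e-08), led by the inflammatory cytokines Il1b (12.3-fold, 3.62 ± 0.42) and Tnf (3.44-fold). The alternative activation and suppression list also moved up: 7 of 17 rose and 2 fell by either count (median 0.55, camera adjusted p = 0.00568, adjusted p = 0.325 with an estimated correlation). Arg1, an arginine-consuming enzyme, was 2.46-fold higher (1.3 ± 0.3, adjusted p = 0.00113) and the cytokine Il10 2.07-fold higher. Of 25 chemokines 16 rose and 1 fell, adjusted over the list alone 16 and 1 (median 0.73, camera adjusted p = 4.58e-09, adjusted p = 0.0525 with an estimated correlation). Xcl1, which attracts cross-presenting dendritic cells, was 6-fold higher and Ccl4 4.6-fold higher. In the Fas and death receptor signalling list 8 of 12 rose and 2 fell, adjusted over the list alone 8 and 2 (median 0.5, camera adjusted p = 0.00114, adjusted p = 0.0786 with an estimated correlation). The death receptor Fas was 1.91-fold higher (0.93 ± 0.12) and its ligand Fasl rose by 1.52 ± 0.14. Of 14 immediate early and heat shock genes 7 rose, 8 adjusted over the list alone (median 0.56, camera adjusted p = 0.00114, adjusted p = 0.092 with an estimated correlation). The transcription factors Egr1 and Atf3 rose by 1.2 ± 0.15 and 1.63 ± 0.23.

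Proliferation genes fell at day 3. All 23 measured cell cycle genes fell, 23 adjusted over the list alone (median -1.39, camera adjusted p = 2.28e-19), including the mitotic checkpoint kinase Bub1b (-1.8 ± 0.14), the spindle motor Kif11 (-1.74 ± 0.15) and Aurka (-1.44 ± 0.12). Of 13 p53 response genes 8 fell and 1 rose, adjusted over the list alone 8 and 1 (median -0.48, camera adjusted p = 0.00133). The largest fall among them was in Gtse1, a gene expressed in the S and G2 phases (-1.61 ± 0.15). Of 15 melanocyte lineage genes 10 fell, 11 adjusted over the list alone (median -0.47, camera adjusted p = 0.00133, adjusted p = 0.325 with an estimated correlation). The melanosomal exchanger Slc24a5 was at -1.02 ± 0.23 and tyrosinase, Tyr, at -0.72 ± 0.2 (adjusted p = 0.00558). Pmel differed by -0.31 ± 0.16 (adjusted p = 0.109) and passed only when the fit used the arrays of the compared groups alone. The largest falls of all genes were in the prokineticin receptor Prokr1 (-2.73 ± 0.2), the cytokinesis protein Anln (-2.24 ± 0.15, adjusted p = 5.56e-12) and Peg10 (-2.11 ± 0.21). Cfap54, Scd1, Neto2, Abca12 and Tmem184c followed, between -2 and -1.92. The lower interquartile range of the IL-12TD day 3 arrays (2.26 against 2.76) went with lower values in bright genes. With all genes divided into 10 equal groups by their Mock day 3 level, the median change was -0.39 in the brightest group and 0.27 in the dimmest. The Mock arrays enter both the grouping and the change, so part of this contrast can come from their noise.

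At day 3, of 10 B cell markers 5 rose by either count, including Ms4a1 (0.67 ± 0.13). The list's call (median 0.34, camera adjusted p = 0.00589, adjusted p = 0.092 with an estimated correlation) was lost after a second quantile normalization (0.16, adjusted p = 0.0878). Of 14 dendritic cell markers 1 rose, the transcription factor Batf3 (0.5 ± 0.16), and 2 fell, and 1 and 2 adjusted over the list alone (median 0.1, camera adjusted p = 0.485). Of 9 mast cell markers 3 rose and 1 fell by either count, with the histamine-forming enzyme Hdc at 2.38 ± 0.24 and the receptor Kit at -0.85 ± 0.21 (median 0.27, camera adjusted p = 0.0869). Of 12 endothelial markers 1 rose and 5 fell, 1 and 6 adjusted over the list alone, with the cadherin Cdh5 at -0.86 ± 0.16 (median -0.35, camera adjusted p = 0.095). Of 12 fibroblast and matrix genes 1 rose, the proteoglycan gene Dcn (1.02 ± 0.22), and 2 fell by either count. Their median was -0.04, the mean 0.01 and the test pointed up (camera adjusted p = 0.89). Of 12 keratinocyte genes 2 rose and 1 fell, Perp (-0.96 ± 0.16), and 1 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.0934). Of 8 adipocyte genes 3 rose by either count. The list's call (median 0.35, camera adjusted p = 0.0257, adjusted p = 0.11 with an estimated correlation) was lost after quantile normalization (0.22, adjusted p = 0.0717) and without Mock day 3 replicate 3 (0.28, adjusted p = 0.0612). Of 11 skeletal muscle genes 3 rose and 0 adjusted over the list alone. That list's call (median 0.32, camera adjusted p = 0.0473, adjusted p = 0.378 with an estimated correlation) was lost after quantile normalization (0.17). It was also lost without any of Mock day 3 replicates 2, 3 and 4 (0.22, 0.3 and 0.22) or IL-12TD day 3 replicates 1 and 3 (0.19 and 0.29). Of 16 hypoxia and glycolysis genes 1 rose and 3 fell, 1 and 1 adjusted over the list alone, with Ndrg1 at 0.53 ± 0.17 and the kinase Pdk1 at -0.85 ± 0.11 (median -0.06, camera adjusted p = 0.583).

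By limma, 8610 of 19938 genes passed at day 3, 3456 higher and 5154 lower in IL-12TD, of which 498 and 619 changed by at least 2-fold. The camera test called 20 lists up and 3 down of the 29. With an estimated correlation between genes 9 of the calls held: interferon gamma response, costimulation, IL-12 and STAT4 signalling, T cell and NK effector, immune checkpoint, cell cycle, p53 response, T cell and neutrophil. The fry test called 26 lists; it asks whether a list's genes move on balance in a single direction and does not compare them with other genes. After a second quantile normalization over the tested genes the count was 5586, with 2408 higher and 3178 lower. Without dim genes 1822 were higher and 5223 lower, or 25.9% higher in place of 40.1%.

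**Figure D2:**
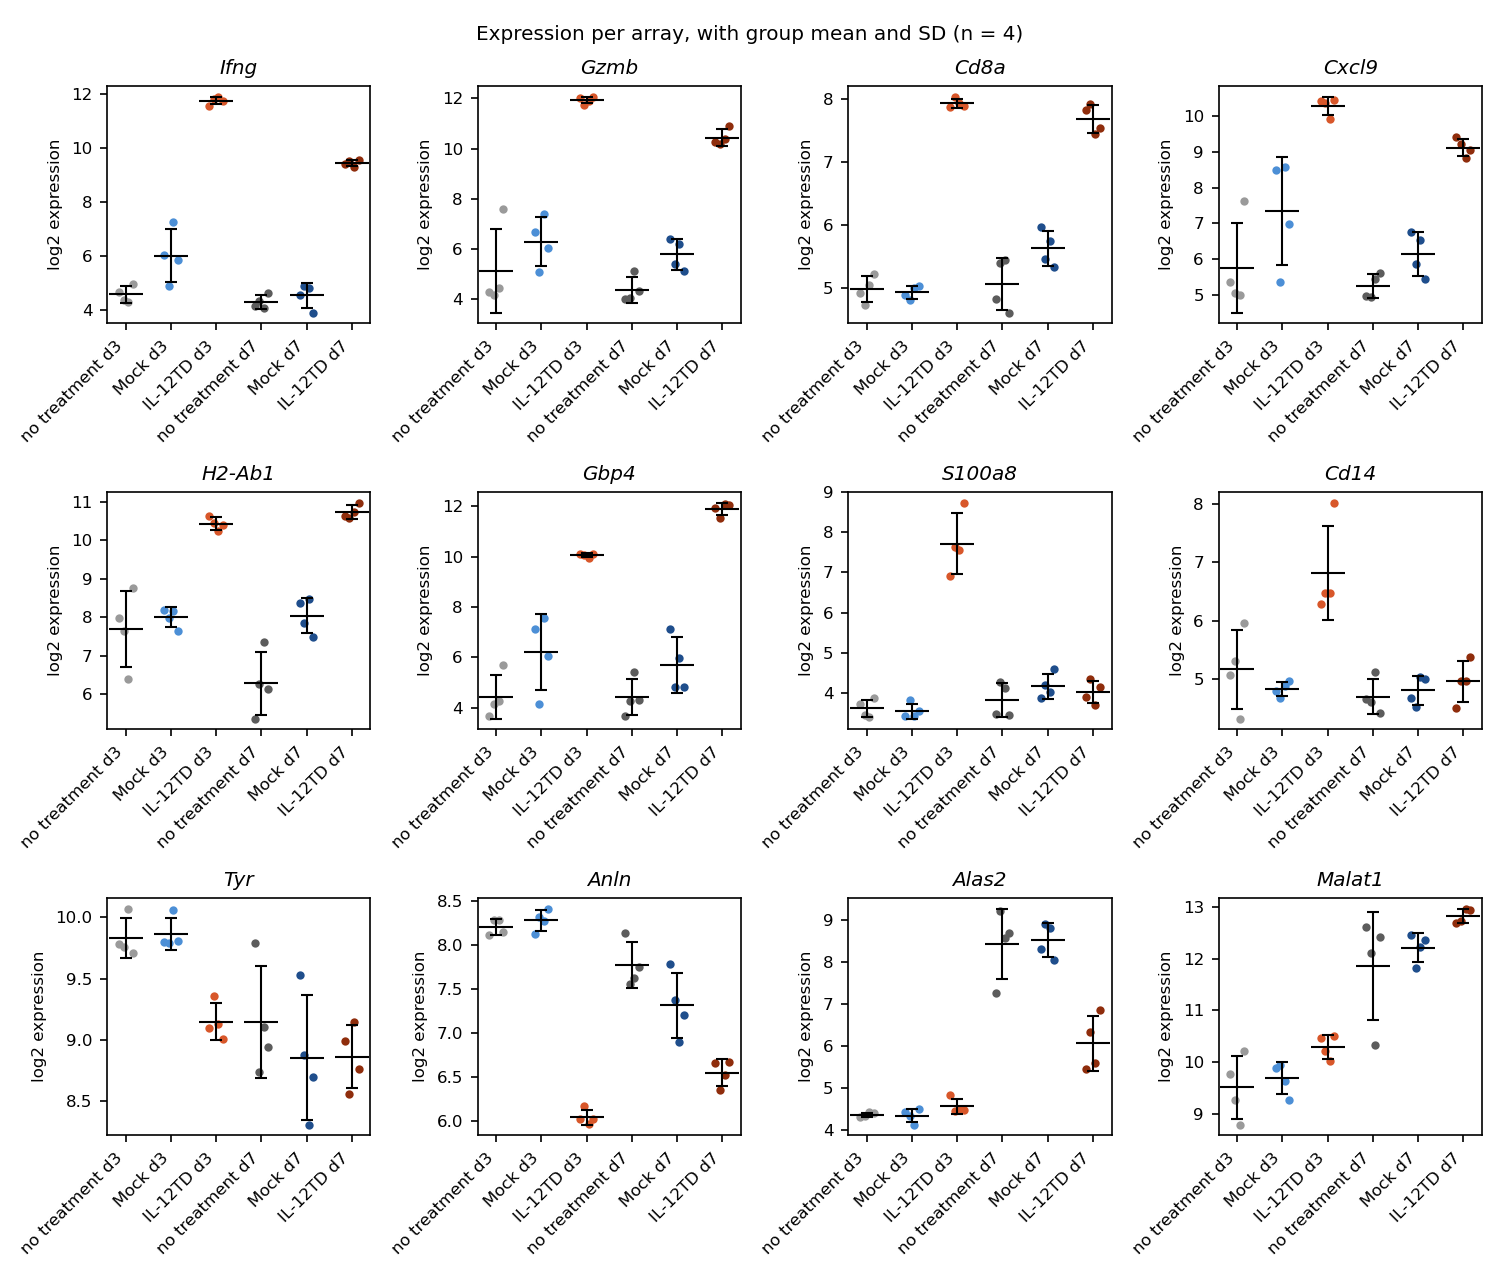
Log2 expression (vertical axis) of 12 genes in the 6 groups (horizontal axis; d3 and d7 are the days), with a point per array and bars for the group mean and SD (n = 4). Ifng lies at 11.74 ± 0.14 in IL-12TD day 3 and at 9.43 ± 0.12 in IL-12TD day 7, above every array of the other groups; S100a8 is raised only in IL-12TD day 3 among the groups shown.

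The same comparison at day 7 asked what the IL-12 transduction changed 4 days later. The 3 largest rises were in interferon-induced GTPases. The guanylate-binding proteins Gbp4, Gbp11 and Gbp8 were 74.2-fold (6.21 ± 0.53, adjusted p = 9.25e-10), 54.8-fold and 41.6-fold higher, with Gbp4 at 11.9 ± 0.25 in IL-12TD and 5.68 ± 1.11 in Mock tumours. Iigp1, an immunity-related GTPase, rose by 4.78 ± 0.4, and Casp12, an inflammatory caspase, by 4.03 ± 0.31. Ifng was 29.5-fold higher (4.88 ± 0.28, adjusted p = 1.09e-12), at 9.43 ± 0.12 against 4.55 ± 0.45, Gzmb was 25.1-fold higher and Cd3g 16.9-fold higher.

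All 20 interferon gamma response genes rose at day 7, 20 adjusted over the list alone, with a median of 3.01 (camera adjusted p = 4.61e-36). They included Gbp5 (14.6-fold), the transcription factor Irf8 (11.5-fold), Cxcl10 (8.23-fold), Cxcl9 (7.85-fold, 2.97 ± 0.5), Nos2 (4.37-fold, 2.13 ± 0.27) and Ciita, the regulator of MHC class II genes (3.64-fold). All 21 type I interferon response genes rose by either count (median 2.14, camera adjusted p = 4.03e-32), with the antiviral GTPase Mx1 at 2.91 ± 0.2 and Ifit2 at 2.69 ± 0.16. Of 15 MHC class I presentation genes 12 rose, 12 adjusted over the list alone (median 1.84, camera adjusted p = 1.03e-16), including Tap1 (6.69-fold, 2.74 ± 0.26) and its partner Tapbp (2.21 ± 0.19). Of 9 MHC class II presentation genes 6 rose, and adjusted over the list alone 6 rose and 1 fell (median 2, camera adjusted p = 8.37e-06, adjusted p = 0.0663 with an estimated correlation). H2-Aa rose by 3.17 ± 0.32 and H2-Ab1 was 6.45-fold higher (2.69 ± 0.34, adjusted p = 1.18e-06). All 14 pan-leukocyte markers rose by either count (median 1.74, camera adjusted p = 4e-17), and Ptprc was 6.03-fold higher (2.59 ± 0.28).

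At day 7 T cell and effector genes also rose. Of 16 T cell and NK effector genes 15 rose, 16 adjusted over the list alone (median 2.06, camera adjusted p = 6.28e-23), including the pore-forming protein Prf1 (6.91-fold, 2.79 ± 0.28). Of 12 IL-12 and STAT4 signalling genes 11 rose by either count (median 1.61, camera adjusted p = 6.41e-17), with Il2ra 13.6-fold higher and the interleukin 18 receptor gene Il18r1 at 2.21 ± 0.13. Of 16 T cell markers 10 rose, 13 adjusted over the list alone (median 1.21, camera adjusted p = 2.38e-15), with Cd8a 4.16-fold higher (2.06 ± 0.16, adjusted p = 3.73e-10) and the costimulatory receptor Cd28 at 1.74 ± 0.16. Of 10 NK cell markers 5 rose, 6 adjusted over the list alone (median 0.57, camera adjusted p = 4.43e-05, adjusted p = 0.149 with an estimated correlation). Of 12 immune checkpoint genes 8 rose, 9 adjusted over the list alone (median 0.93, camera adjusted p = 9.4e-09), with Cd274 10.8-fold higher and Entpd1, the ectonucleotidase CD39, at 2.12 ± 0.27. Of 12 Fas and death receptor genes 9 rose and 1 fell by either count (median 0.84, camera adjusted p = 1.54e-08); the necroptosis effector Mlkl was 4.18-fold higher and Fas 1.53-fold higher (0.61 ± 0.12, adjusted p = 0.000268). Il12a differed by 0.18 ± 0.13 (adjusted p = 0.322). Il12b differed by 0.44 ± 0.14 (adjusted p = 0.0266), a call lost without any of Mock day 7 replicates 2 and 4 (0.39 and 0.37) or IL-12TD day 7 replicates 2, 3 and 4 (0.4, 0.41 and 0.42).

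At day 7, of 18 macrophage and monocyte markers 10 rose, 14 adjusted over the list alone (median 0.83, camera adjusted p = 7.78e-06, adjusted p = 0.217 with an estimated correlation). The complement gene C1qb was 2.44-fold higher (1.29 ± 0.27) and the efferocytosis receptor Mertk rose by 0.87 ± 0.18. Of 16 neutrophil and granulocyte markers 1 rose and 0 adjusted over the list alone (median -0.17, camera adjusted p = 0.536). In the costimulation and myeloid activation list 7 of 19 rose and 1 fell, 7 and 2 adjusted over the list alone (median 0.35, camera adjusted p = 0.00109, adjusted p = 0.122 with an estimated correlation). The receptor gene Slamf7 rose by 2.05 ± 0.25 and the cytokine gene Il18 by 0.96 ± 0.17. In the alternative activation and suppression list 5 of 17 rose by either count. Its median was -0.02, its mean 0.15 and the test pointed up (camera adjusted p = 0.29). Arg1 differed by 0.08 ± 0.3 (adjusted p = 0.874). Of 25 chemokines 6 rose, 6 adjusted over the list alone, among them Cxcl11 (1.87 ± 0.22) and Ccl5 (1.36 ± 0.15). The chemokine median was 0.05 (camera adjusted p = 0.0627), and the list passed without Mock day 7 replicate 2 (adjusted p = 0.0411), Mock day 7 replicate 3 (0.00936) or IL-12TD day 7 replicate 3 (0.0156). Of 14 dendritic cell markers 1 rose, the endocytic receptor Ly75 (4.91-fold, 2.3 ± 0.2), and 2 fell by either count. Their median was -0.09, the mean 0.03 and the test pointed down (camera adjusted p = 0.852).

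Of the 8 largest falls at day 7 the first was Alas2, the erythroid enzyme that starts heme synthesis, at 6.06 ± 0.66 in IL-12TD and 8.52 ± 0.41 in Mock tumours (-2.46 ± 0.29, adjusted p = 2.58e-07). The list of erythroid genes had too few measured members for a test: 2 of 4 fell, with a median of -0.71. The other falls were in Scd1 (-2.02 ± 0.22), the matricellular protein Ccn1 (-1.95 ± 0.22), the cytokine receptor Cntfr (-1.9 ± 0.16), Dnm1, the sterol sensor Insig1, Cep152 and Fbxl7, the last 4 between -1.59 and -1.39. Of 23 cell cycle genes 15 fell, and adjusted over the list alone 19 fell and 1 rose (median -0.52, camera adjusted p = 1.79e-07, adjusted p = 0.122 with an estimated correlation). Cdc20, an activator of mitotic exit, was at -1 ± 0.15 and the kinase Cdk1 at -0.78 ± 0.12. Of 13 p53 response genes 2 rose and 1 fell by either count (median 0.09, camera adjusted p = 0.564). Of 15 melanocyte lineage genes 2 rose and 1 fell by either count, with Rab38, which serves melanosome transport, at 0.77 ± 0.15. The melanocyte median was 0.21 (camera adjusted p = 0.0881) and passed without Mock day 7 replicate 1 (0.39, adjusted p = 0.00103), IL-12TD day 7 replicate 2 (0.31, adjusted p = 0.0217) or replicate 4 (0.27, adjusted p = 0.0421). Tyr differed by 0.01 ± 0.2 (adjusted p = 0.971), and Pmel by 0.21 ± 0.16 (adjusted p = 0.353), or 0.39 (adjusted p = 0.0448) without Mock day 7 replicate 1.

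Few members of the remaining lists passed at day 7. Of 16 hypoxia and glycolysis genes 3 fell by either count, including the carbonic anhydrase Car9 (-1 ± 0.14). The hypoxia median was -0.07 (camera adjusted p = 0.485), and -0.2 (adjusted p = 0.0109) after quantile normalization. Of 14 immediate early and heat shock genes 4 rose, and adjusted over the list alone 4 rose and 2 fell, with Jun at 0.87 ± 0.17. Their median was -0.13, the mean 0.11 and the test pointed up (camera adjusted p = 0.523). Of 10 B cell markers 1 fell and 0 adjusted over the list alone (median -0.23, camera adjusted p = 0.132). Of 9 mast cell markers Kit rose (0.81 ± 0.21), the median was -0.1 and the mean 0 (camera adjusted p = 0.793). Of 12 endothelial markers 1 rose and 3 fell by either count, with Emcn at -0.95 ± 0.17 (median -0.19, camera adjusted p = 0.132). Of 12 fibroblast and matrix genes 2 rose, Fap (0.75 ± 0.15) and Dcn (0.88 ± 0.22), and 1 fell. Their median was -0.06, the mean 0.02 and the test pointed up (camera adjusted p = 0.992). The keratinocyte list moved down with 1 of 12 fallen, Perp (-1.16 ± 0.16; median -0.25, camera adjusted p = 0.0112, adjusted p = 0.217 with an estimated correlation), a call lost after quantile normalization (-0.21, adjusted p = 0.0574). The skeletal muscle list moved up with 4 of 11 risen by either count, including the myosin Myh1 (0.9 ± 0.17). Its call (median 0.24, camera adjusted p = 0.00793, adjusted p = 0.347 with an estimated correlation) was lost without dim genes (0.19, adjusted p = 0.212) and without IL-12TD day 7 replicate 1 (0.15, adjusted p = 0.0686). Of 8 adipocyte genes 1 rose (median -0.14, camera adjusted p = 0.852).

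By limma, 4333 genes passed at day 7, 2573 higher and 1760 lower in IL-12TD, of which 678 and 49 changed by at least 2-fold. After a second quantile normalization the split of the calls was 2289 higher and 2574 lower, or 47.1% higher in place of 59.4%, and with array weights in the fit 7947 genes passed, 3924 higher and 4023 lower. The camera test called 14 lists up and 2 down. Of these calls 9 held with an estimated correlation: interferon gamma response, type I interferon response, MHC class I presentation, Fas and death receptor signalling, IL-12 and STAT4 signalling, T cell and NK effector, immune checkpoint, pan-leukocyte and T cell.

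**Figure D3:**
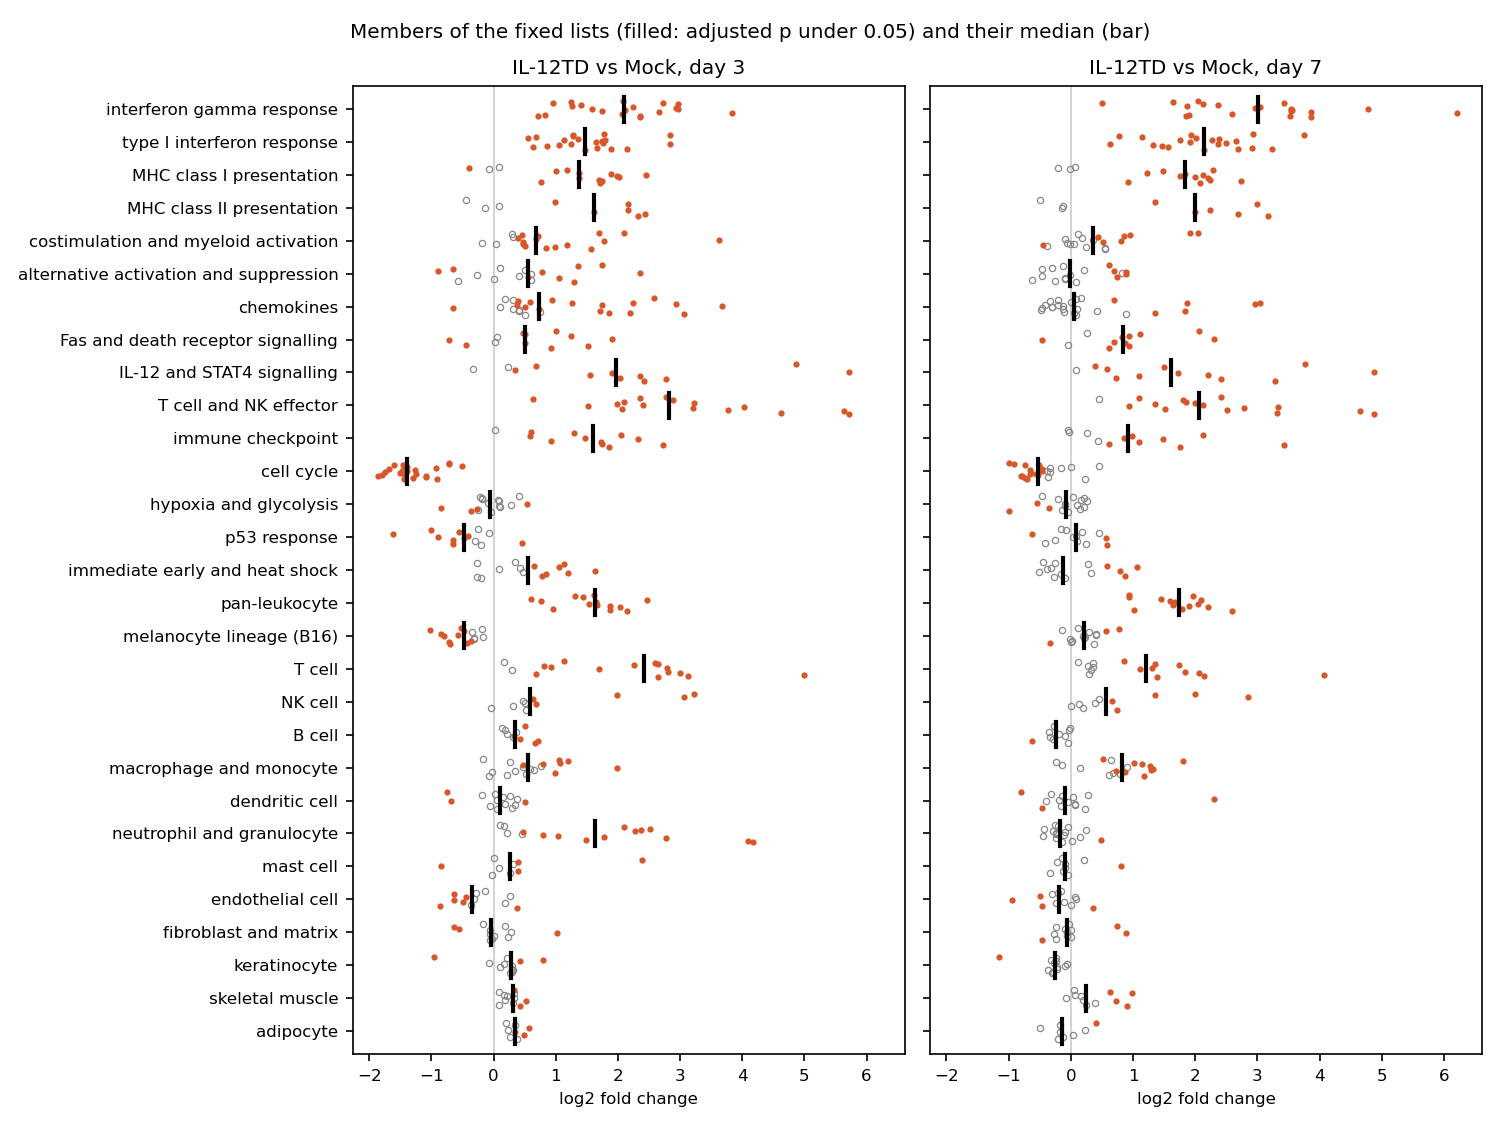
Log2 fold change of IL-12TD against Mock tumours (horizontal axis) for the measured members of 29 gene lists (vertical axis), at day 3 on the left and day 7 on the right. Filled points passed at an adjusted p under 0.05, open points did not, and the black bar is the list median (interferon gamma response 2.09 and 3.01, neutrophil and granulocyte 1.63 and -0.17).

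The difference between the days was itself tested as an interaction. The neutrophil and granulocyte list had a smaller IL-12TD minus Mock difference at day 7, with 12 of 16 members passing and 14 adjusted over the list alone (median -1.55, camera adjusted p = 1.62e-08, adjusted p = 0.236 with an estimated correlation). S100a8 (-4.31 ± 0.36) and S100a9 (-4.08 ± 0.37) led it. The T cell list also had a smaller difference at day 7, with 10 of 16 passing and 12 adjusted over the list alone (median -0.75, camera adjusted p = 4.01e-05, adjusted p = 0.236 with an estimated correlation). Cd8a was among them (-0.95 ± 0.23, adjusted p = 0.00267). The interferon gamma response list had a larger difference at day 7, with 11 of 20 passing and 0 passing the other way, the same adjusted over the list alone (median 1.02, camera adjusted p = 0.00254, adjusted p = 0.476 with an estimated correlation). Gbp4 (2.38 ± 0.74) and Iigp1 (1.83 ± 0.57) were among them. The cell cycle list was less far below Mock at day 7, with 19 of 23 passing and 20 adjusted over the list alone (median 0.88, camera adjusted p = 1.86e-07, adjusted p = 0.236 with an estimated correlation). Its mean level did not rise in IL-12TD tumours (7.01 ± 0.06 at day 3, 6.86 ± 0.09 at day 7). The level was lower at day 7 in Mock tumours (8.31 ± 0.1 and 7.34 ± 0.22), so the smaller difference went with the Mock arm. The melanocyte lineage list, with a median of -0.47 at day 3 and 0.21 at day 7, had 10 of 15 members higher in this test and 13 adjusted over the list alone (median 0.73, camera adjusted p = 0.00153, adjusted p = 0.429 with an estimated correlation). Ifng itself differed between the days by -0.84 ± 0.4 (adjusted p = 0.0893). In total 8467 genes passed, 4800 upward and 3667 downward, and 4998 after a second quantile normalization, 2581 upward and 2417 downward. Without dim genes 4805 passed upward and 1664 downward. Of the genes called at each day, 717 were higher at both days, where 446 would be shared if the days were independent, and 648 were lower at both, where 455 would be. Another 734 were lower at day 3 and higher at day 7, where 665 would be, and 268 were higher at day 3 and lower at day 7, where 305 would be. Both days were called in a single fit that shares each gene's residual spread, so genes with a small spread pass more easily at both days. The numbers under independence are therefore no test of shared effects. Across the 19938 genes, which are not independent replicates, the changes at the 2 days correlated with a Pearson r of 0.228 and a Spearman rho of -0.135. The r was 0.134 without Mock day 7 replicate 1, and rho was -0.215 without that array, -0.0831 without Mock day 7 replicate 3 and -0.0891 without IL-12TD day 3 replicate 3. The rho turned positive after quantile normalization (0.0158) and without dim genes (0.00997).

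Scores relative to the pan-leukocyte list asked whether a group of genes moved more or less than leukocyte markers as a whole. Each score is an array's mean log2 value of a list minus that of the pan-leukocyte list, compared by an exact permutation test of 4 against 4 arrays, two-sided, with Benjamini-Hochberg adjustment over the 16 comparisons. At day 3 the T cell score was higher in IL-12TD than in Mock by 0.47, and at day 7 it was lower by a difference of -0.48 (exact p = 0.0286, adjusted p = 0.0381 for both). The day 7 T cell call was lost after quantile normalization (-0.38, exact p = 0.114) and without dim genes (-0.41, exact p = 0.0571). The interferon gamma response score was higher by 1.26 at day 7 (exact p = 0.0286, adjusted p = 0.0381) and by 0.48 at day 3 (exact p = 0.114, adjusted p = 0.14), or 0.29 without Mock day 3 replicate 2. Macrophage scores differed by -0.95 and -0.9, dendritic cell scores by -1.52 and -1.67 and alternative activation scores by -1.04 and -1.56 at days 3 and 7 (exact p = 0.0286, adjusted p = 0.0381 for each). The neutrophil score differed by 0.11 at day 3 (exact p = 0.743) and by -1.82 at day 7 (exact p = 0.0286, adjusted p = 0.0381). The day 3 value was -0.07 without IL-12TD day 3 replicate 4, -0.1 after quantile normalization and 0.6 (exact p = 0.0286) without dim genes. MHC class I scores differed by -0.31 at day 3 (exact p = 0.0286) and -0.19 at day 7 (exact p = 0.429). MHC class II scores differed by -0.32 (exact p = 0.0286) and -0.18 (exact p = 0.229), with the class II values turning to 0.04 at day 3 and 0.29 at day 7 without dim genes. At day 7 the class I score was -0.33 without Mock day 7 replicate 3, and without Mock day 7 replicate 1 the class I and class II scores were -0.07 and -0.09. Lists of dim genes change less on a log scale, which limits comparisons between lists.

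In IL-12TD against untreated tumours Ifng and Gzmb rose most at day 3, and Gbp4 and Gzmb at day 7. At day 3 Ifng was 142-fold higher (7.15 ± 0.28), Gzmb 112-fold, Gbp4 49.4-fold, Gzma 48.3-fold and Cd3g 38.8-fold, and Prokr1 (-2.68 ± 0.2), Peg10, Anln, Abca12 and Cfap54 fell most. At day 7 Gbp4 was 178-fold higher (7.48 ± 0.53), Gzmb 67.1-fold, Gbp8 63.8-fold, Gbp11 63-fold and Iigp1 51.2-fold, while Scd1 (-2.59 ± 0.22), Alas2 (-2.38 ± 0.29), Cntfr, Ccn1 and Timp4 fell most. Cd8a was 7.74-fold and 6.14-fold higher, H2-Ab1 6.66-fold and 22-fold, Cxcl9 22.8-fold and 14.6-fold, Tap1 5.22-fold and 12.2-fold, Nos2 10.4-fold and 6.99-fold, Ptprc 6.14-fold and 10.9-fold, and Arg1 3.08-fold and 2.22-fold at days 3 and 7. Fas was 1.92-fold and 1.53-fold higher. The dim Il12a was 1.29-fold higher at day 3 (adjusted p = 0.0245) and 1.31-fold at day 7 (adjusted p = 0.032). Il12b was 1.32-fold higher at day 3 (adjusted p = 0.0241) and 1.48-fold at day 7 (adjusted p = 0.00378). Tyr differed by -0.68 ± 0.2 at day 3 (adjusted p = 0.00783) and by -0.28 ± 0.2 at day 7 (adjusted p = 0.378). All 20 interferon gamma response genes rose at both days, with medians of 2.58 and 3.69, and all 16 T cell and NK effector genes rose, with medians of 3.08 and 2.46. Cell cycle genes fell, 23 of 23 at day 3 and 21 of 23 at day 7 (medians -1.4 and -0.82); for these 3 lists the counts adjusted over the list alone were the same. These comparisons called 8353 genes at day 3 (3210 higher, 5143 lower) and 4062 at day 7 (2346 higher, 1716 lower), and 24 and 17 lists, of which 13 and 12 held with an estimated correlation. Without dim genes the day 3 split was 1770 higher and 5232 lower. The day 7 split was 2035 higher and 2443 lower after quantile normalization, and 1808 higher and 2790 lower after centring each array on its median. The labels state no irradiation for the untreated mice, so irradiation, T cells and IL-12 cannot be separated here.

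Mock tumours were compared with untreated tumours at each day. By limma 0 genes passed at day 3 (329 at an unadjusted p under 0.05, where chance gives 997) and 0 at day 7 (2767 at an unadjusted p under 0.05). At day 3 Ifng differed by 1.43 ± 0.28 (adjusted p = 0.54), Cxcl9 by 1.58 ± 0.5 (adjusted p = 1) and Cd8a by -0.05 ± 0.16 (adjusted p = 1). At day 7 H2-Ab1 differed by 1.77 ± 0.34 (adjusted p = 0.0864), Arg1 by 1.08 ± 0.3 (adjusted p = 0.214), Cd8a by 0.56 ± 0.16 (adjusted p = 0.221) and Ptprc by 0.85 ± 0.28 (adjusted p = 0.231). Without Mock day 3 replicate 2 the day 3 count was 7, with Ifng at 1.8 and passing. At day 7 it was 9 without Mock day 7 replicate 4, 6 without no treatment day 7 replicate 3 and 3 without Mock day 7 replicate 1. With no treatment day 3 replicate 4, no treatment day 7 replicate 3 and Mock day 7 replicate 1 left out together, chosen after the results were seen, 409 genes passed at day 7 (162 higher, 247 lower) and 3 at day 3. An exchange of the 2 day 7 arrays named last between the arms gave 1412 genes. H2-Ab1 passed without Mock day 7 replicate 4 (1.95) and without no treatment day 7 replicate 3 (2.13). It also passed after quantile normalization (1.95, adjusted p = 0.0462; 9 genes in all) and with array weights (6 genes in all). Centring gave 1 gene at day 7, and array weights 1 gene at day 3. At day 3 the interferon gamma response list had a median of 0.45 with 5 of 20 members risen adjusted over the list alone (camera adjusted p = 2.36e-22, adjusted p = 0.077 with an estimated correlation). Its median was 0.72 without no treatment day 3 replicate 4 and 0.29 without Mock day 3 replicate 3. At day 7 the pan-leukocyte list had a median of 0.7 with 11 of 14 risen adjusted over the list alone (camera adjusted p = 1.04e-08, adjusted p = 0.174 with an estimated correlation). The MHC class II list had a median of 1.05 with 7 of 9 risen adjusted over the list alone (camera adjusted p = 1.97e-07, adjusted p = 0.174 with an estimated correlation). The cell cycle list had a median of -0.3 with 8 of 23 fallen adjusted over the list alone (camera adjusted p = 7.99e-11, adjusted p = 0.174 with an estimated correlation). The camera test called 13 lists at day 3 and 21 at day 7, with an estimated correlation 0 and 0, and fry called 0 and 10.

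Between day 3 and day 7 the erythroid enzyme gene Alas2 and the noncoding RNAs Malat1 and Gas5 rose in every arm. Alas2 was 16.8-fold higher at day 7 in untreated tumours (4.07 ± 0.29, adjusted p = 1.9e-10), 18.1-fold higher in Mock tumours (4.18 ± 0.29), and higher by 1.5 ± 0.29 in IL-12TD tumours. Of the 4 measured erythroid genes 2 rose in untreated tumours (median 1.32), 3 in Mock (1.06) and 1 in IL-12TD tumours (0.32). Malat1, a nuclear noncoding RNA, rose by 2.34 ± 0.32, 2.52 ± 0.32 and 2.52 ± 0.32 in the untreated, Mock and IL-12TD arms. In no treatment day 7 replicate 3 it lay at 10.33, near the highest untreated day 3 array (10.21), and in the other untreated day 7 arrays at 12.1 to 12.61. Gas5, a host gene of small nucleolar RNAs, rose by 2.92 ± 0.18, 2.33 ± 0.18 and 2.77 ± 0.18. Rmrp, Rnu3a, Rbm25 and Lncpint were also higher in all 3 arms, by 1.61 to 3.34. Ly96, a co-receptor of the lipopolysaccharide receptor, fell by 2.66, 2.82 and 2.33 on the log2 scale. The dim Il12a rose by 0.37 ± 0.13, 0.6 ± 0.13 and 0.39 ± 0.13 in the untreated, Mock and IL-12TD arms. It passed in each arm, also where no transduced cells were given. Day and processing batch cannot be told apart, since the labels give no batch and each array is of a single day.

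In untreated tumours the largest falls after Ly96 were in the chemokine Ccl8 (-2.36 ± 0.38), the proton pump subunit Atp6v0d2 (-2.26 ± 0.36), the scavenger receptor Cd36 (-2.25 ± 0.36) and the interferon-induced Ifit3 (-2.12 ± 0.26). There 14 of 18 macrophage markers fell and 1 rose, the same adjusted over the list alone (median -0.93, camera adjusted p = 0.000633, adjusted p = 0.485 with an estimated correlation). H2-Ab1 was at -1.42 ± 0.34 and Arg1 at -1.25 ± 0.3. Of 21 type I interferon genes 15 fell, and 15 fell and 1 rose adjusted over the list alone (median -1.01, camera adjusted p = 2.76e-05, adjusted p = 0.485 with an estimated correlation). Of 23 cell cycle genes 19 fell and 2 rose, with 19 and 3 adjusted over the list alone (median -0.69, camera adjusted p = 2.49e-06, adjusted p = 0.485 with an estimated correlation). In Mock tumours Uprt, Stxbp4, Rnase2a and Tbc1d7 fell most after Ly96, by 2.48 to 2.2 on the log2 scale. There 19 of 23 cell cycle genes fell by either count (median -1.11, camera adjusted p = 4.58e-10, adjusted p = 0.255 with an estimated correlation). Ifng fell by 1.47 ± 0.28 there, Tyr fell by 1.01 ± 0.2, and Cd8a rose by 0.7 ± 0.16. In IL-12TD tumours the granzymes Gzmg (12.4-fold, 3.63 ± 0.52) and Gzmd (10.4-fold, 3.38 ± 0.58) rose most, followed by Lncpint, Gdap10 and Phxr4. The largest falls there were in Cxcl2, a neutrophil chemoattractant (-4.07 ± 0.48), S100a8 (-3.69 ± 0.25), Ccl3 (-3.61 ± 0.4), Hcar2 (-3.32 ± 0.43) and S100a9 (-3.22 ± 0.26). Ifng fell by 2.31 ± 0.28 (adjusted p = 4.39e-07) and Arg1 by 1.72 ± 0.3, while Cd8a differed by -0.25 ± 0.16 (adjusted p = 0.239). Gzmb fell by 1.5 ± 0.51 (adjusted p = 0.019), a call lost with a trended and robust variance prior (adjusted p = 0.052). Of 16 neutrophil markers 12 fell by either count (median -1.33, camera adjusted p = 3.46e-06, adjusted p = 0.573 with an estimated correlation). Of 25 chemokines 14 fell and 1 rose, with 16 and 1 adjusted over the list alone (median -0.7, camera adjusted p = 4.51e-05, adjusted p = 0.573 with an estimated correlation). Of 17 alternative activation genes 12 fell and 2 rose by either count (median -0.96, camera adjusted p = 0.00494, adjusted p = 0.822 with an estimated correlation).

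By limma 7070 genes changed with time in untreated tumours (2250 higher at day 7, 4820 lower), 10152 in Mock (4747 higher, 5405 lower) and 8330 in IL-12TD tumours (4030 higher, 4300 lower). In untreated tumours the split was 2484 higher and 2894 lower after quantile normalization, and after centring it was 3421 higher and 5858 lower in Mock and 3369 higher and 5764 lower in IL-12TD tumours. Without dim genes the splits were 1685 higher and 4916 lower in untreated, 2971 and 5415 in Mock, and 3793 and 3057 in IL-12TD tumours. Over all probesets of the table they were 6077 higher and 6272 lower in untreated, 8883 and 7239 in Mock, and 8213 and 7497 in IL-12TD tumours. The majority thus turned to higher in Mock and IL-12TD tumours in this setting. The interquartile range was lower at day 7 by a difference of -0.36 in untreated and -0.54 in Mock tumours (exact permutation p = 0.0286 for both, n = 4), and higher by 0.19 in IL-12TD tumours (exact permutation p = 0.0857). With an estimated correlation 0 list calls held in any arm.

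**Figure D4:**
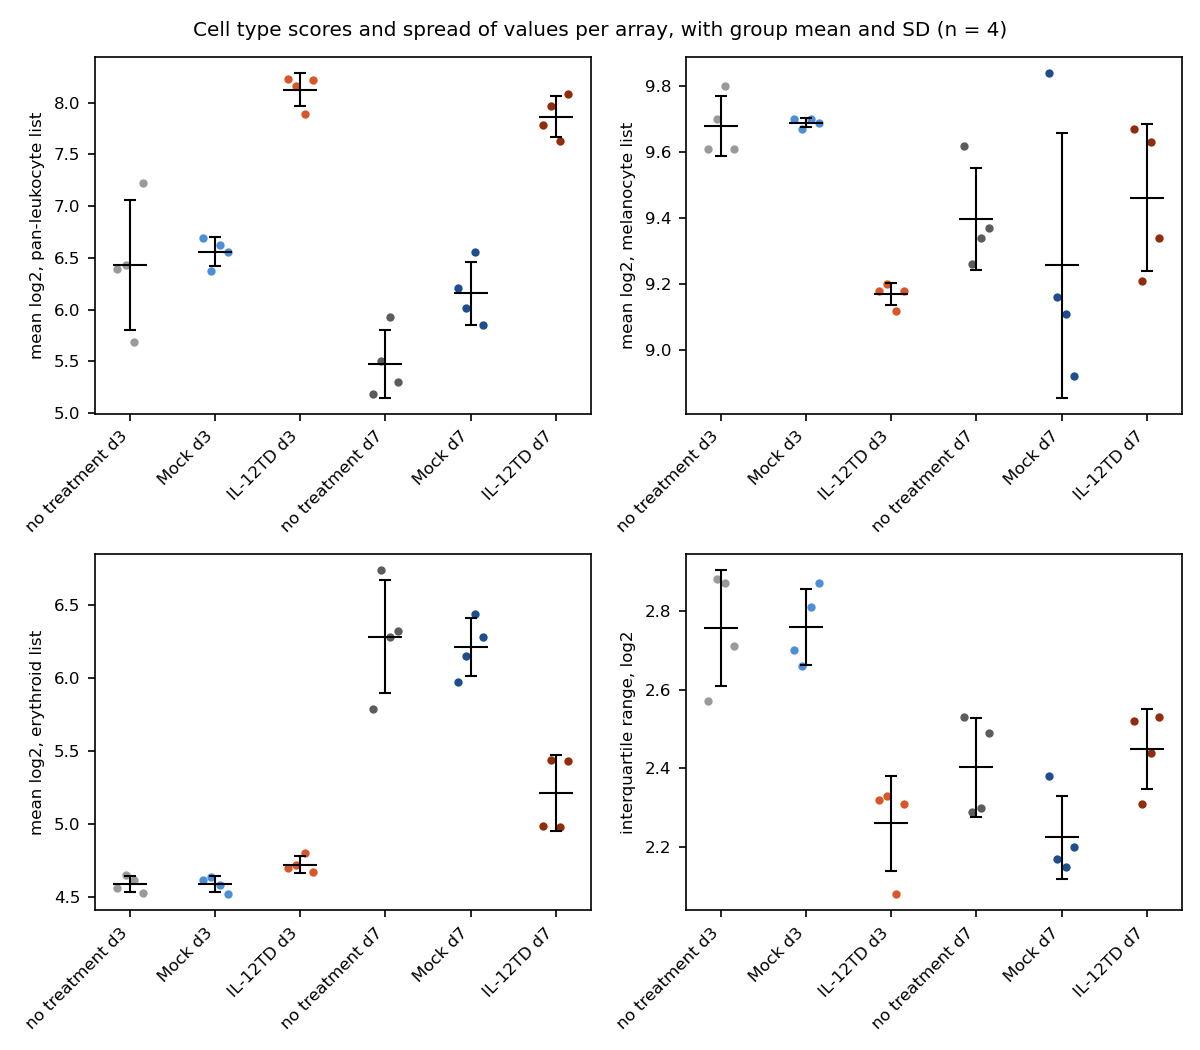
Mean log2 expression of the pan-leukocyte, melanocyte and erythroid lists and the interquartile range of the log2 values of the tested genes (vertical axes). The 6 groups are on the horizontal axes, where d3 and d7 are the days, with a point per array and bars for the group mean and SD (n = 4). The pan-leukocyte score was 8.12 ± 0.16 in IL-12TD day 3 and 7.86 ± 0.2 in IL-12TD day 7, and the erythroid score was 6.28 ± 0.39 in no treatment day 7 and 5.21 ± 0.26 in IL-12TD day 7.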

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

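The splits of the arrays were planned before the results, as were the exact tests of list scores. Exchanging arrays between the compared groups asked whether chance could give as many called genes. For IL-12TD against Mock at day 3, 1 of 35 splits, the real one, gave 8610 genes and the highest other gave 1. At day 7 it was also 1 of 35, with 4333 in the real split and 3576 in the highest other. That other split exchanges Mock day 7 replicate 1 and IL-12TD day 7 replicate 2, and was the only 1 of 34 over 100 genes. On the third principal component (14.9% of the variance) this Mock array lay at 11.3, the other Mock day 7 arrays at -26.7 to -31.7. This IL-12TD array lay at 16.7, the other IL-12TD day 7 arrays at 36.2 to 43.1. A structure of the samples apart from treatment may thus add to the day 7 count. For IL-12TD against no treatment the real split also gave the most genes, at day 3 (8353 against 472) and day 7 (4062 against 691). The same holds for day 7 against day 3 in untreated (7070 against 2962), Mock (10152 against 2667) and IL-12TD tumours (8330 against 917), each 1 of 35. For the difference between the days the real split was 1 of 100 drawn (8467 against 2759). These are the smallest shares that the splits can give. Splits that mix the groups put the group difference into the residual spread, so they usually call few genes whatever the cause. The counts therefore make chance less likely but do not exclude it. For Mock against no treatment the real split gave 0 genes at either day, so 35 of 35 splits reach it by construction and the splits say nothing about chance there. The highest other split there gave 34 genes at day 3, and 1412 at day 7. That split set no treatment day 7 replicate 3 and Mock day 7 replicates 2, 3 and 4 against the other 4 arrays, which points to a structure of the samples.

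At day 3 many genes changed a little between IL-12TD and Mock while the arrays had different ranges, and the tests of this pattern were chosen after the result was seen. Of the 8610 called genes 7493 changed by less than 2-fold, with interquartile ranges of 2.26 in IL-12TD and 2.76 in Mock arrays (exact permutation p = 0.0286, n = 4 per group). A second quantile normalization kept 99.8% of the calls of at least 2-fold, 1115 of 1117, so their call and direction did not depend on the range. Calls this large are hard to lose, and whether the range added to their size was not tested. Of the calls under 2-fold it kept 48.2%, or 3613, and 3880 were lost or turned, so a narrower range may account for many of the small changes. A larger leukocyte share as the source of the narrower range stays open: in untreated tumours the range was also lower at day 7 (-0.36, exact permutation p = 0.0286, n = 4 per group) while the leukocyte score differed by -0.95 (exact permutation p = 0.0571).

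The interferon gamma response list differed more between IL-12TD and Mock at day 7 than at day 3 (median 1.02, with 17 of 20 members larger), and the tests of leukocyte share and of Ifng were chosen after the result was seen, the test of the array range before. The list's median change from day 3 to day 7 was 0.63 in IL-12TD and -0.43 in Mock tumours, so both arms enter the pattern. After quantile normalization the median difference was 0.74 (0.65 to 0.89 with each array left out, camera adjusted p = 0.00097). This argues against a narrower range as the whole cause, but the range may account for part of the 1.02. The list's score relative to leukocytes was higher at day 7 than at day 3 by 0.75 in IL-12TD tumours (exact permutation p = 0.0286, n = 4 per group) and differed by -0.03 in Mock tumours (exact permutation p = 0.971), which argues against a larger leukocyte share. A larger Ifng difference at day 7 was not seen: Ifng fell between the days in IL-12TD (-2.31 ± 0.28) and in Mock tumours (-1.47 ± 0.28), and the difference of these, -0.84 ± 0.4, did not pass (adjusted p = 0.0893). The pattern stays open, since the list's call was lost with an estimated correlation (adjusted p = 0.476) and without dim genes.

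Of the 4 measured erythroid genes 2 rose between day 3 and day 7 in untreated and 3 in Mock tumours, and 2 fell in IL-12TD against Mock at day 7; of the tests of this pattern that of a mislabelled array was chosen after the result was seen. After quantile normalization the median change with time in untreated tumours was 1.28 (lowest with an array left out 1.11), which argues against a narrower range as the cause. The erythroid score of no treatment day 7 replicate 3, which lies nearest to day 3, was 6.28, and those of the untreated day 3 arrays 4.53 to 4.65; a day 3 array labelled day 7 would lower the day 7 mean, so this value does not bear on the cause. The 4 probesets shared by several globin genes moved the same way as these genes, by a median of 6.57 with time in untreated tumours and -1.96 for IL-12TD against Mock at day 7, and all 4 passed in both, so red blood cells or their precursors in the samples may account for it. Whether the blood came from the tumours or from their dissection, and whether day or batch set it, stays open.

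Arrays outside the range of their group by Dixon's ratio made up 21 of 270 groups tested, where chance gives about 5 per 100. The 45 measures come from the same arrays and include both lists and some of their members. The tests are therefore not independent, and the 21 cannot be set against chance as if they were. In no treatment day 3 replicate 4 the interferon gamma response list was at 6.49, T cell and NK effector at 5.55, mast cell at 4.22, Cxcl9 at 7.64, Tap1 at 7.84 and Gzmb at 7.61. In IL-12TD day 3 replicate 3 the interquartile range was 2.08, the type I interferon response list at 8.39 and p53 response at 6.7. In IL-12TD day 3 the immediate early and heat shock list was at 7.47 in replicate 4 and Il12a at 4.54 in replicate 1. In Mock day 7 replicate 3 costimulation and myeloid activation was at 5.17, adipocyte at 5.01 and Nos2 at 5.67. In Mock day 3 alternative activation and suppression was at 5.82 in replicate 1 and Tyr at 10.06 in replicate 3. In no treatment day 7 replicate 3 macrophage and monocyte was at 6.02 and Tap1 at 6.18, and in replicate 1 endothelial cell was at 5.1. Adipocyte was at 4.87 in no treatment day 3 replicate 1, and Il12b at 4.72 in IL-12TD day 7 replicate 1.

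The IL-12TD minus Mock difference itself differed between the days for 8467 genes and 13 lists at the preset correlation. With an estimated correlation 0 of the list calls held (adjusted p = 0.236 to 0.739 with an estimated correlation). Lists with a larger value at day 7 were interferon gamma response (1.02), type I interferon response (0.67), cell cycle (0.88), p53 response (0.72) and melanocyte lineage (0.73). Lists with a smaller value were costimulation and myeloid activation (-0.21), chemokines (-0.52), T cell and NK effector (-0.66), immediate early and heat shock (-0.6), T cell (-0.75), B cell (-0.66), neutrophil and granulocyte (-1.55) and keratinocyte (-0.48). Single lists lost the call with some array left out, for type I interferon response with Mock day 3 replicate 3 (0.55) or Mock day 7 replicate 4 (0.58). For costimulation these were Mock day 3 replicate 2 (-0.15) and IL-12TD day 3 replicate 4 (-0.32). For immediate early they were Mock day 3 replicate 2 (-0.63), IL-12TD day 3 replicate 4 (-0.54), Mock day 7 replicate 4 (-0.48) and IL-12TD day 7 replicate 2 (-0.67).

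Among single genes the day 7 minus day 3 value of the difference was positive for Tap1 (0.99, adjusted p = 0.0334), Tyr (0.73, adjusted p = 0.0402), Gbp4 (2.38), Gbp11 (2.22), Gbp8 (2.32), Iigp1 (1.83) and Casp12 (1.4). It was positive as well for genes with large falls at day 3: Prokr1 (1.56), Anln (1.47), Peg10 (2.22), Cfap54 (1.18), Neto2 (1.83), Abca12 (0.62) and Tmem184c (1.96). It was negative for Cd8a (-0.95, adjusted p = 0.00267), Il2ra (-1.1), Gzma (-1.3), Arg1 (-1.22, adjusted p = 0.0232), S100a8 (-4.31) and S100a9 (-4.08). It was negative too for Alas2 (-2.68, adjusted p = 4.16e-05), Ccn1 (-2.18), Cntfr (-0.66), Dnm1 (-0.95) and Cep152 (-1.12).

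Probesets not used in the tests also changed between IL-12TD and Mock: 407 of those with several genes passed at day 3 and 541 at day 7, and 1469 and 722 of those with no gene listed.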

How the results depend on the processing

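In the comparisons of IL-12TD with Mock every list and named gene that was called kept its direction in every setting. Counts of genes moved by more than 1.5 times in a few settings. A second quantile normalization gave 5586 genes for IL-12TD against Mock at day 3 and 4998 for the difference between the days. Array weights gave 7947 for IL-12TD against Mock at day 7. Using all probesets of the table, which adds probesets by construction, gave 6230 for IL-12TD against no treatment at day 7 and 12349, 16122 and 15710 for time in untreated, Mock and IL-12TD tumours. Elsewhere the cause was not tested.

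Mock against no treatment gave 0 genes at either day in the primary fit. At day 3 array weights gave 1, and leaving out single arrays gave 0 to 7 (7 without Mock day 3 replicate 2). At day 7 it was 9 with quantile normalization, 1 with centring, 6 with array weights and 0 to 9 with single arrays left out (9 without Mock day 7 replicate 4). Leaving out no treatment day 3 replicate 4, no treatment day 7 replicate 3 and Mock day 7 replicate 1 together, chosen after the results were seen, gave 3 at day 3 and 409 at day 7; the cause was not tested.

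Leaving out single arrays gave 6898 to 8278 genes for IL-12TD against Mock at day 3 and 3008 to 5525 at day 7. With an estimated correlation 9 lists were called at day 3 and 9 at day 7. In Mock against no treatment at day 3, leaving out no treatment day 3 replicate 3 turned alternative activation and suppression to -0.11, pan-leukocyte to -0.15 and macrophage and monocyte to -0.22, and leaving out replicate 4 gave 0.4, 0.36 and 0.26; the cause was not tested. Residuals of arrays with the same replicate number correlated with a median of -0.013, as did the others. Pairs over r = 0.1 were 18 of 60 with the same number (highest 0.52) and 42 of 180 others (highest 0.31). Some pairing by replicate number is therefore not excluded. A replicate block gave 8624 and 4354 genes for IL-12TD against Mock at days 3 and 7.

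Of the scores relative to pan-leukocyte, 3 changed side in some setting: MHC class II presentation without dim genes (0.04 at day 3, 0.29 at day 7), and neutrophil and granulocyte at day 3 after quantile normalization (-0.1) and without IL-12TD day 3 replicate 4 (-0.07). The cause was not tested. The last was 0.6 without dim genes, and the T cell score at day 7 was -0.38 after quantile normalization and -0.41 without dim genes, short of the threshold. The Pearson r of the day 3 and day 7 changes was 0.372 after quantile normalization, 0.362 without dim genes and 0.134 (without Mock day 7 replicate 1) to 0.279 (without IL-12TD day 3 replicate 3). The Spearman rho turned to 0.0158 after quantile normalization and 0.00997 without dim genes, and ran from -0.215 (without Mock day 7 replicate 1) to -0.0831 (without Mock day 7 replicate 3); the cause was not tested. Signal near background limits dim genes, whose changes are compressed.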

Other observations

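Genes of sterol and fatty acid synthesis were lower in IL-12TD than in Mock tumours. A list of 29 such genes, of which 25 were measured, was composed after falls of Scd1, Insig1, Msmo1 and Fads1 had been seen. Those 4 were left out of it, and the values of its members had not been seen. At day 3, 24 of the 25 fell (median -0.93, camera p = 7.36e-12, p = 0.0233 with an estimated correlation). They included Cyp51, a sterol demethylase (-1.65 ± 0.23), the fatty acid synthase Fasn (-1.48 ± 0.21), the squalene epoxidase Sqle (-1.29 ± 0.18) and Hmgcs1, an early enzyme of the mevalonate pathway (-1.04 ± 0.17). At day 7, 14 fell and 1 rose, the acetyl-CoA carboxylase Acaca (0.73 ± 0.17), with a median of -0.46 (camera p = 3.21e-06, p = 0.109 with an estimated correlation), and Cyp51 was at -1.1 ± 0.23. The score of the list minus the melanocyte lineage score differed between IL-12TD and Mock by -0.66 at day 7 and -0.4 at day 3 (exact permutation p = 0.0286 for both, n = 4 per group). In Mock against no treatment 0 members passed at either day by limma, with medians of 0.03 at day 3 (camera p = 0.0144, p = 0.388 with an estimated correlation) and -0.29 at day 7 (camera p = 6.51e-08, p = 0.0664 with an estimated correlation). Between day 3 and day 7 members of the list also fell in every arm: 19 of 25 fell in untreated, 23 in Mock and 12 in IL-12TD tumours, where 1 rose (medians -0.5, -0.88 and -0.39). After quantile normalization these medians were -0.19, -0.46 and -0.49. The camera p with an estimated correlation was 0.119, 0.0402 and 0.261.

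The 2 probesets shared by several MHC class I heavy chain genes, for which no single gene can be named, rose in IL-12TD against Mock by 1.77 ± 0.28 and 1.82 ± 0.22 at day 3 and by 2.17 ± 0.28 and 2.15 ± 0.22 at day 7.

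Whether the arrays of the 2 days were processed together is not stated, and the labels give no batch. Genes raised at day 7 in every arm, such as Malat1 (2.34, 2.52 and 2.52 in the untreated, Mock and IL-12TD arms), are therefore values without an attribution. For Malat1, no treatment day 7 replicate 3 lay near the untreated day 3 arrays. Protein levels, cell counts and tumour size were not analysed here.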
